A study of Sus scrofa with 2 samples.

How the data were processed

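RNA was measured in porcine (Sus scrofa) follicular granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle, from Chinese Erhualian pigs. Cells received either a control siRNA or an siRNA against SMAD4, the common-mediator SMAD that carries TGF-beta, activin and BMP receptor signals into the nucleus. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of 3 individuals per group was pooled in equal amounts, and 1 library per group was made with the Ion Total RNA-Seq Kit and sequenced on an Ion Torrent Proton instrument. The labels do not say whether both groups came from the same animals, so any difference can be one between animals. The genome build, the annotation, the aligner and the read counter behind the values are not given in the sources used here. The deposited values are RPKM scaled by the upper quartile, per the names of the deposited tables. What else was done to make them is not given in the sources used here. They were used as deposited.

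Read depth was taken from the values themselves. For the 16239 genes above 0 in both libraries, 665 had values at the ratio 0.908163 after rounding to 6 decimals, the commonest ratio. With 1 divisor per library, 890 for control and 980 for SMAD4 siRNA, all 18428 genes above 0 in either library gave whole reads at a whole transcript length of up to 40000 bases, within a relative tolerance of 2e-09 and an absolute tolerance of 1e-06. The smallest such whole numbers were used, so the reads and lengths given are lower bounds. Gene length below means this smallest length. At the median length of 1648 bases, a value of 1 stands for 1.47 reads in the control library, and for slightly more in the SMAD4 siRNA library. Each ratio of values has an exact Clopper-Pearson 95% interval from the split of a gene's reads over both libraries. These intervals cover counting error only: they hold neither the spread between animals nor that between transfections, and reads without molecular identifiers are not independent molecules.

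The comparison was SMAD4 siRNA over control siRNA. The main measure was log2 of (SMAD4 siRNA value + 1) over (control value + 1), among genes with a mean value of at least 1. That scale understates the change of genes with low values, so for single genes plain ratios of the values are printed. Medians of lists stay on that scale, also where they are given as folds. A gene counted as higher or lower at a log2 ratio of at least 1 in size. With 1 library per group there is no test between the conditions and no replicate check of any difference. The number of genes that counting error alone would carry past 2-fold was found by redrawing the split of each gene's reads 100 times with no difference between libraries. For each of 25 gene lists and 6 cell type marker lists, all written at the same stage as the rule of size, before any value was seen, the median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins (seed 1), where at least 5 members were measured. The percentile describes these libraries. The lists for pancreatic acinar genes, MHC class I and MHC class II were written after some values had been seen.

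The genes named are SMAD4, up to 3 members at each end of a list, the 15 highest and 15 lowest log2 ratios among genes with a symbol, reads in both libraries and a larger value of at least 5, and the 10 highest values of each library. Some were chosen after their values were seen: those at the ends among genes with at least 100 reads, and SMAD2, SMAD3, MX1, IRF7, CCNB1, MKI67, MCM4, PCNA, THBS1, TGFBI, ID1, ID2, SMAD7, CTGF, ACVR1, ACVR1B, FN1, COL1A1, FSHR, FOXL2, B2M, SLA-3, PSMB8, TAP1, TAP2 and the pancreatic genes, together with every gene mentioned as listed at 0. Names came from the deposited tables and from a reference table of assembly Sscrofa11.1, used for names alone: of 19902 IDs without a symbol, 1556 received one, and 240 older symbols were renamed. For 538 genes this gave a second entry under one name, so their reads may be split over 2 entries. SMAD4 has a single entry. Some genes that the rule takes are not reported here.

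Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, centring on the median or on a trimmed mean of log2 ratios, rescaling each library to the same sum as for TPM, other minimums on the mean value, 1.5-fold and 4-fold thresholds, list means, and unmatched random lists. Chosen after seeing the data were a minimum of 100 reads over both libraries, counting intervals that exclude 1, mRNA entries alone, random lists matched also on gene length (10 expression bins by 5 length bins), and symbols of the deposited tables alone.

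The steps were tested on simulated data drawn for the 18428 genes of this comparison from their real read totals. The step between the libraries was found. The divisors were given and not searched for, so that 100% of the simulated genes with reads gave whole reads was certain beforehand. The smallest whole reads equalled those drawn for 85.7% of these genes and divided them evenly for the rest, whose intervals come out too wide. The simulation started from the smallest lengths, so 85.7% does not tell how often the real reads are exact. Of genes changed 1.5-fold, 3-fold, 4-fold and 8-fold, 50 at each size and each with at least 100 reads, the 2-fold rule took 2%, 100%, 100% and 100%. A simulated list of 20 genes shifted by 0.5 on the log2 scale lay above all its random lists, and 4 of 100 unshifted lists lay outside the central 95%. The counting intervals covered 95.3% of 1000 simulated ratios, drawn with counting error alone. Exact intervals cover at least 95% of such draws by design, so this checks the calculation and not the real reads. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.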

Results

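Total RNA of porcine granulosa cells was sequenced from 1 control siRNA library and 1 SMAD4 siRNA library, each made from a pool of 3 individuals. The tables list 34570 genes, of which 17277 were above 0 in the control library and 17390 in the SMAD4 siRNA library. The libraries held at least 17680952 and 17394711 reads on genes. Messenger RNA took 92.5% of these reads in the control library and 92.9% in the SMAD4 siRNA library, and ribosomal RNA took 3.28% and 2.66%. The highest value in the control library belonged to ACTA2, the smooth muscle actin, with 3.87% of these reads against 2.69% in the SMAD4 siRNA library. All these shares are of smallest whole reads, which can fall short of the true ones by factors that differ between genes. RN18S, TMSB10, TIMP1 and ACTB came next in the control library, and RN18S had the highest value in the SMAD4 siRNA library. There are no replicates, so every difference is one between 2 libraries, and each range in parentheses after a ratio is a 95% counting interval.

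The comparison asked which transcripts differ in granulosa cells when SMAD4, the shared mediator of TGF-beta and BMP signalling, is knocked down. SMAD4 itself was lower in the library labelled SMAD4 siRNA. Its value was 85.0 in the control library, from at least 656 reads, and 47.9 in the SMAD4 siRNA library, from at least 407 reads. The ratio was 0.563 (0.497 to 0.639), a log2 ratio of -0.81. SMAD9 was at a ratio of 0.585, SMAD3 at 0.912 and SMAD2 at 1.01, while SMAD1 and SMAD5 were listed at 0 in both libraries.

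Several groups of genes stood apart between these libraries. Interferon-stimulated genes were higher, with a median log2 ratio of 1.27 over 26 measured members, or 2.42-fold on the scale of value + 1 that all list medians use. Mitosis genes were higher too, with a median of 1.96-fold on that scale over 22 members, followed by DNA replication genes with 1.44-fold over 17. Response genes of TGF-beta and BMP signalling were lower, with a median ratio of 0.685 over 16 members. Extracellular matrix genes (median ratio 0.815) and actin cytoskeleton genes (median ratio 0.801) were lower by less.

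Among the 16609 genes with a mean value of at least 1, 1191 were higher by at least 2-fold and 1110 were lower by at least 2-fold after SMAD4 siRNA. Counting error alone, drawn on the smallest whole reads, gave 675 higher (610 to 730 over 100 draws) and 651 lower (594 to 717), which is the larger part of both counts. Where the true reads are more, counting error gives fewer. Among the 9664 genes with at least 100 reads, a minimum chosen after seeing the data, 128 were higher and 108 lower, where counting error gave a mean of 0.12 and 0.09. A counting interval excluded 1, in either direction, for 5682 of the 16609 genes. Genes with more reads have narrower intervals, so lists of strongly expressed genes have many such intervals even where changes are small. The median log2 ratio of all measured genes was -0.05. Rescaling each library to the same sum added 0.12 to every log2 ratio of plain values. It would turn ratios between 0.921 and 1 to the other side of 1. With both libraries rescaled to the sum of TPM values, all values are smaller and the minimum and pseudocount weigh more. There 208 genes were higher and 112 lower, and the median log2 ratio of genes with a mean value of at least 1 was 0.06.

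**Figure D1:**
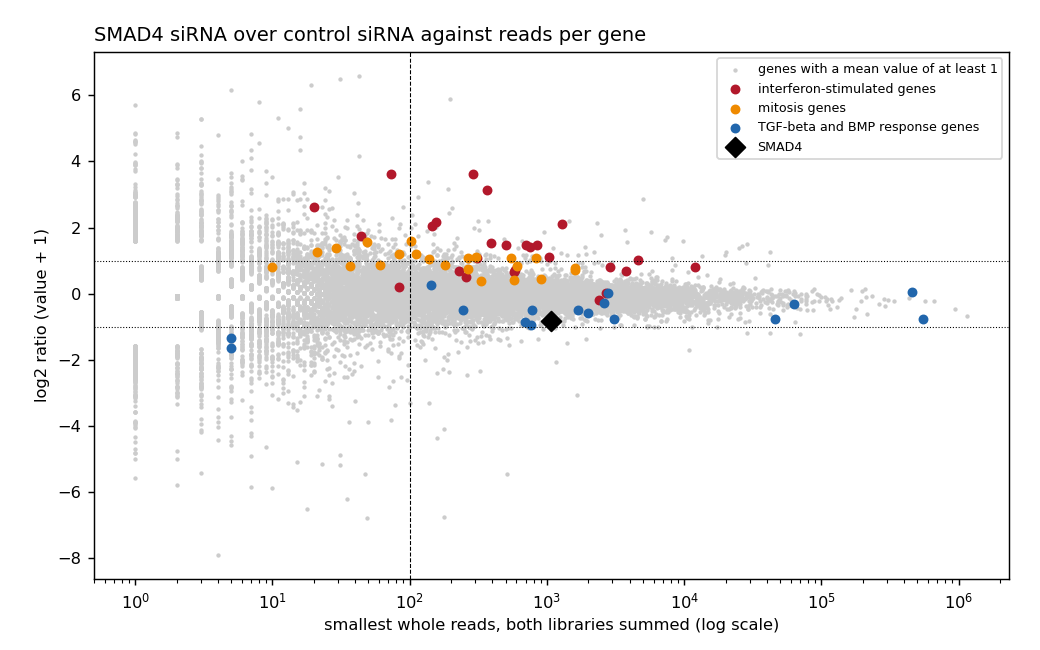
Each point is a gene with a mean value of at least 1, placed by its smallest whole reads summed over both libraries (x axis, log scale) and its log2 ratio of (value + 1), SMAD4 siRNA over control siRNA (y axis). Coloured points are members of 3 lists, the diamond is SMAD4 at -0.81, dotted lines mark 2-fold and the dashed line marks 100 reads. Ratios spread widely below 100 reads, where 6945 of the 16609 genes lie.

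Interferon-stimulated genes, which cells switch on when they sense type I interferon or foreign RNA, had the highest median of the 25 gene lists. Of the 26 measured, 25 had a log2 ratio above 0 and 16 were higher by at least 2-fold, and 23 had a counting interval wholly above 1. OASL, a member of the oligoadenylate synthetase family, went from 3.41 to 53.4, a ratio of 15.7 (5.85 to 59.1) on 4 and 69 reads. RSAD2, the antiviral enzyme viperin, went from 7.01 to 96.6, a ratio of 13.8 (8.55 to 23.6). OAS1, which makes the second messenger that activates RNase L, went from 48.1 to 429, a ratio of 8.92 (6.26 to 13.1). MX1, an antiviral GTPase, had a ratio of 1.74 (1.67 to 1.80), and IRF7, the regulator of type I interferon genes, had 2.18. BST2, the surface protein tetherin, had 4.27 (3.70 to 4.95). At the other end, STAT2 was at 0.875 (0.807 to 0.948), IRF1 at 1.01 and IFIH1 at 1.15. ISG15 was listed at 0 in both libraries. The list median of 1.27 on the log2 scale lay above all 10000 matched random lists, whose central 95% ran from -0.20 to 0.09, and members with at least 100 reads had a median of 1.10.

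Mitosis genes were all on the higher side: 22 of 22 measured members had a log2 ratio above 0, and 11 were higher by at least 2-fold. CDK1, the kinase that drives entry into mitosis, went from 19.7 to 61.4, a ratio of 3.12 (1.94 to 5.20). BUB1B, a spindle checkpoint kinase, had a ratio of 3.14 (1.57 to 6.80), and CENPE, a kinetochore motor, had 5.68 (1.96 to 22.4) on 4 and 25 reads. CCNB1, the mitotic cyclin, went from 90.1 to 192. The smallest ratios were those of KIF23 (1.32), ANLN (1.34) and MKI67 (1.36). The list median of 0.97 lay above all random lists. For DNA replication, 16 of 17 members were above 0, with a median of 0.53 that also lay above all random lists. CDT1 and CDC6, which load the replicative helicase, had ratios of 2.33 (1.85 to 2.97) and 2.04 (1.33 to 3.20). The helicase subunit MCM4 had 1.58, the polymerase clamp PCNA 1.54, and RRM1, a ribonucleotide reductase subunit, 0.873. Over the genes of G1 control the median was 0.16, inside its random range (96.1st percentile). Within that list E2F1, a transcription factor for S-phase genes, went from 105 to 222, a ratio of 2.11 (1.79 to 2.49), and CDKN2B, a CDK inhibitor known as a TGF-beta target, from 85.8 to 41.5, a ratio of 0.483 (0.366 to 0.635).

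**Figure D2:**
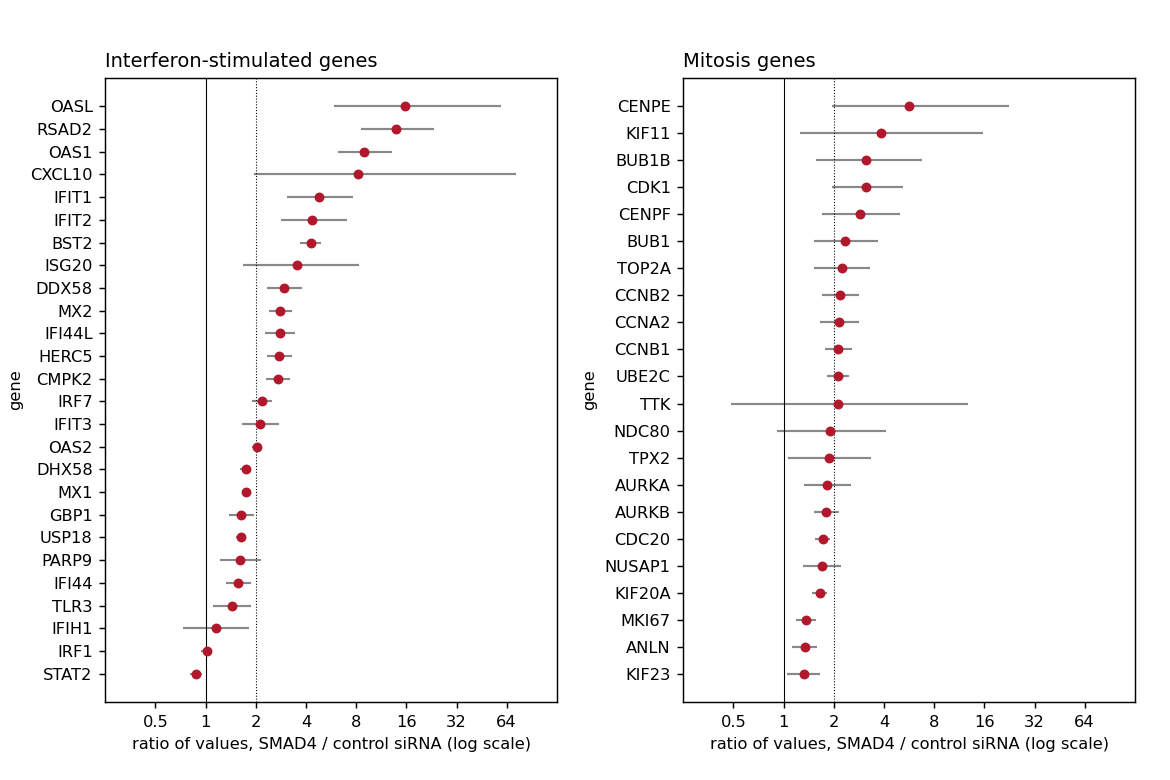
Ratios of values, SMAD4 siRNA over control siRNA, on a log scale (x axis) for each measured interferon-stimulated gene (left) and mitosis gene (right). Points are ratios, bars are 95% counting intervals from the reads, the solid line marks 1 and the dotted line 2. All mitosis genes lie to the right of 1, from 1.32 for KIF23 to 5.68 for CENPE, and STAT2 at 0.875 is the single interferon-stimulated gene to the left of it.

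The response genes of TGF-beta and BMP signalling were lower together, with 13 of 16 members below 0 and 12 with a counting interval wholly below 1. Their sizes were modest, and the 2 members lower by at least 2-fold, HEY1 (5 and 0 reads) and ID4 (4 and 1 reads), rest on very few reads. SMAD6, an inhibitory SMAD made in response to BMPs, went from 186 to 95.7, a ratio of 0.513 (0.441 to 0.596). SMAD7, its counterpart in TGF-beta signalling, had a ratio of 0.663, and ID2, a BMP-induced inhibitor of helix-loop-helix factors, had 0.585. The matrix proteins TGFBI and THBS1 had ratios of 0.555 and 0.583, the latter from 64287 to 37502. CTGF had 0.808 and ID1 0.829. TGIF1 (1.02), TIMP1 (1.04) and SKIL (1.21) were the highest, and ID3 was listed at 0 in both libraries. The median of -0.55 lay below all 10000 random lists (central 95% from -0.23 to 0.10).

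Receptors and SMADs gave a mixed picture, with a median of -0.13 inside the random range. Of 16 measured, 5 had an interval wholly below 1 and 0 had one wholly above 1. The share excluding 1 in either direction is near that of all measured genes, 5682 of 16609. It does not speak to the shared direction of the 5. Among the 5 were TGFBR2, the ligand-binding TGF-beta receptor, at 0.564 (0.495 to 0.643), BMPR2 at 0.594, ACVR1B at 0.610 and ACVR1 at 0.667. TGFBR3 had a ratio of 1.88 on 14 and 29 reads. Ligands and binding proteins had a median of -0.17, also inside the range. TGFB3 was at 0.524 (0.475 to 0.577), whereas TGFB1 was at 1.69 (1.47 to 1.94) and INHBA, the subunit of activin A, at 1.31 (1.22 to 1.41).

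Structural genes were lower in the SMAD4 siRNA library. For the actin cytoskeleton and smooth muscle list, 14 of 15 members were below 0, each with an interval below 1, though none by 2-fold. VCL, a focal adhesion protein, had a ratio of 0.560 (0.547 to 0.573), TPM1 0.596, MYLK, the kinase that triggers actomyosin contraction, 0.604, and ACTA2 0.622 (from 549693 to 341635). DES alone was higher, at 1.16 (1.11 to 1.22). The median of -0.32 was at the 0.01 percentile of random lists. In the matrix list 18 of 24 were below 0 and 17 had an interval wholly below 1, with a median of -0.30 at the 0.01 percentile. MMP9, a secreted gelatinase, went from 131 to 50.5, a ratio of 0.385 (0.306 to 0.481). LUM had a ratio of 0.583, FBN1, the core of microfibrils, 0.588 and FN1 0.658, while COL1A1 was at 1.06, POSTN at 1.16 and COL18A1 at 1.34. Theca cell markers, which share DCN and COL3A1 with the matrix list, had a median of -0.16 over 6 members, inside their random range.

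Genes of granulosa function went both ways. Steroid hormone synthesis had a median of 0.16 over 11 members (97.2nd percentile, inside the range), and of 0.04 over the 8 with at least 100 reads. HSD3B1, which makes progesterone from pregnenolone, went from 12334 to 23378, a ratio of 1.90 (1.85 to 1.94). STAR had 6 and 15 reads. CYP11A1 and CYP19A1 were listed at 0 in both libraries, as were the widely expressed POR and FLNA, so a listed 0 says nothing of expression. Of 595 genes in the 25 lists, 60 were listed at 0 in both libraries. For granulosa receptors and identity genes the median was -0.17 over 18 members. IGFBP5, a binding protein of insulin-like growth factors, went from 634 to 249, a ratio of 0.393 (0.324 to 0.476), IGFBP4 was at 1.37 (1.29 to 1.46) and FOXL2, a granulosa identity factor, at 1.11 (0.874 to 1.40). FSHR had only 9 and 7 reads. Ovulation and cumulus expansion genes had a median of -0.27, at the 2.49 percentile and so barely outside the range. With random lists matched also on gene length it was at 3.32, inside the range. In that list RUNX2, a transcription factor of the ovulatory response, had a ratio of 0.300 (0.202 to 0.436) and EREG, an EGF-like growth factor, 3.18 (1.41 to 8.07) on 8 and 28 reads.

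Survival and death genes showed no shared direction beyond random lists: medians were -0.18 for pro-survival genes, -0.16 for pro-apoptotic genes and -0.03 for p53 targets. CASP8, the initiator caspase of death receptors, went from 21.5 to 4.28 on 32 and 7 reads, a ratio of 0.199 (0.0740 to 0.458). MCL1 was at 0.717 (0.677 to 0.758), FOXO1 at 0.708 (0.655 to 0.765) and FAS at 0.725 (0.592 to 0.887). The nuclear-encoded respiratory chain was the other list above its range, by a small amount: 46 of 71 members were above 0, with a median of 0.07 against a central 95% from -0.13 to 0.01. It was inside the range of random lists not matched on expression, and its median was 0.18 with both libraries rescaled to the sum of TPM values. NDUFA6, a subunit of complex I, had the highest ratio, 2.24 (1.54 to 3.30). Inside their ranges lay inflammatory NF-kB genes (median 0.04), immediate early genes (0.00), the unfolded protein response (0.02), glycolysis and hypoxia (-0.12), oxidative stress defence (-0.12), YAP targets (-0.13), cholesterol synthesis (-0.15), ribosomal proteins (-0.04) and histones (-0.21). The pattern for ribosomal proteins also took in 9 S6 kinase genes, without which the median was -0.04. CCL5, a chemokine in the NF-kB list, had a ratio of 4.41 (3.96 to 4.93), and SOD2 had 0.762.

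**Figure D3:**
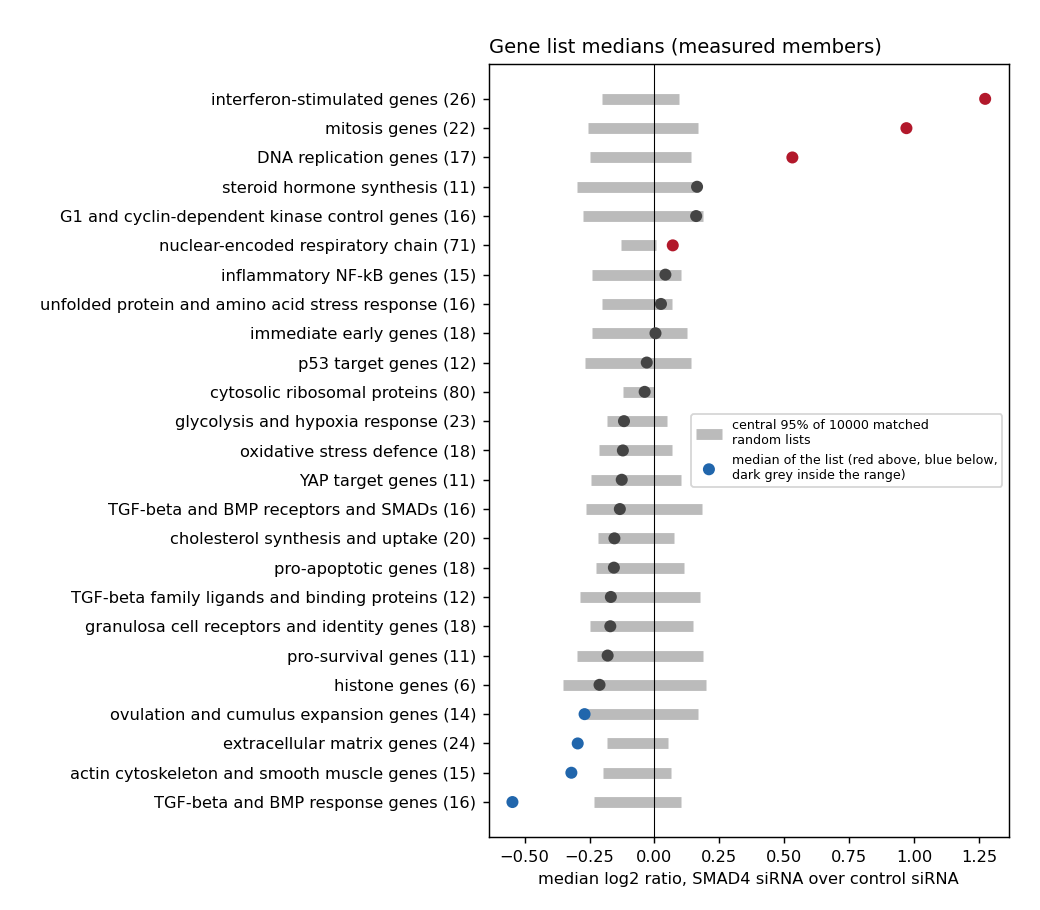
Median log2 ratio, SMAD4 siRNA over control siRNA (x axis), of each of the 25 gene lists, with the number of measured members after its name (y axis). Points are list medians and bars the central 95% of 10000 random lists matched on mean expression. 4 lists lie above their bar, led by interferon-stimulated genes at 1.27, and 4 below, led by TGF-beta and BMP response genes at -0.55.

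In all, 8 of 25 lists lay outside the central 95% of their random lists, where 1.25 would by definition of that range. The 1.25 holds for lists of genes drawn at random. Members of a real list can move together between any 2 libraries, so more lists may lie outside without an effect of the siRNA. Among markers of other cells, leukocyte markers had a median of -0.18 over 7 members and endothelial markers 0.18 over 7, both inside their ranges. Few of these members had many reads. The 3 endothelial markers with at least 100 reads had a median of -0.19, with ERG at 0.582 (0.442 to 0.763) and PECAM1 at 0.875 (0.793 to 0.964). The third was on the higher side, at the list median of 0.18. CD14, the single leukocyte marker with as many reads, was at 0.978 (0.888 to 1.08). All 11 measured pancreatic acinar genes, a list written after CPA1 and CPB1 had been seen, were lower. The size of their median was set by the pseudocount, since 5 had no reads in the SMAD4 siRNA library: it was -2.85 with a pseudocount of 1, -5.63 with 0.1 and -1.71 with 5. The 9 members other than CPA1 and CPB1 had a median of -2.64, or -1.95 over 8 with those at 0 reads set to 3 reads. Erythroid, surface epithelium and oocyte markers had 2, 3 and 2 measured members, too few to rank, with medians of -0.66, -0.02 and 0.16.

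Among single genes with at least 100 reads, the highest ratios belonged to MED29, a Mediator subunit (2 and 196 reads, ratio 89.0, 24.3 to 740), RSAD2, ASB9 at 11.5 (6.07 to 24.6), OAS1, EIF2S2 at 7.80 (4.28 to 15.6) and APRT, an enzyme of adenine salvage, at 6.15 (4.06 to 9.67). S100A11, a calcium-binding protein, went from 2571 to 9453, a ratio of 3.68 (3.44 to 3.93). The lowest were CPA1, a pancreatic carboxypeptidase (501 and 11 reads, ratio 0.0199, 0.00989 to 0.0360), ENY2 at 0.187 (0.119 to 0.285), CDH4, a cadherin, at 0.229 (0.143 to 0.355), CTRB2 at 0.280 and CYP27A1, the sterol 27-hydroxylase, at 0.292 (0.212 to 0.398). AGT, the precursor of angiotensins, was at 0.351 (0.271 to 0.450). MED29 and CDH4 are entries listed under IDs without a symbol and named from the reference table. How reads were assigned to entries is not known, and the intervals do not cover it. Extreme ratios of single genes may therefore not be changes in expression. Without that minimum the ends of the ranking were largely genes with a handful of reads in 1 library, such as TNFSF13B (1 and 25 reads) and CD300C (16 and 1 reads).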

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

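Minimums of 100 reads, intervals excluding 1, mRNA entries alone, length matching and symbols of the deposited tables alone were chosen after seeing the data. Genes lower by at least 2-fold numbered 1110, against 437 with a pseudocount of 5, 112 with each library rescaled to the same sum as for TPM, 546 with a mean value of at least 5, 108 with at least 100 reads, 434 with an interval excluding 1, 705 among mRNA entries, 2277 at 1.5-fold and 351 at 4-fold. Genes higher numbered 1191, against 466, 208, 572, 128, 433, 730, 2245 and 378 in the same order. Fewer genes under stricter minimums and thresholds follow from those settings themselves. Most 2-fold calls are of genes with under 100 reads, and rescaling, which lowers all values, makes the pseudocount and the minimum weigh more. SMAD4 was at -0.58 after that rescaling, outside its counting interval, as the shift of 0.12 and the heavier pseudocount add up, and between -0.83 and -0.77 under the other 4 alternatives. Between 6 and 9 of 25 lists lay outside their random range under the 12 alternatives. Those for interferon, mitosis, replication, TGF-beta response, matrix and actin stayed on their side under all 12, the respiratory chain under 11, and the ovulation list under 4. Centring moves all genes alike, so it could not move a list against its random lists. The alternatives drew fewer random lists than the main value. That alone took the ovulation list, at the edge of its range, inside it under both centrings. Steroid synthesis and NF-kB genes, inside their ranges, left them under 1 each. Over 272 genes, taken by the naming rule or added to it, and 5 alternatives each, 1193 of 1360 log2 ratios stayed inside the counting interval and 167 left it. No 2-fold call could change sign under these alternatives, since pseudocounts keep the sign and the shifts, of at most 0.12, are too small. Depth limits the many weak genes: 6945 of 16609 measured genes had under 100 reads, and no setting replaces the missing replicates.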

Other observations

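The tests on leukocytes, counting noise, the duplex, theca cells and the other acinar genes were chosen after the results were seen, as were the MHC and acinar lists. MHC class I antigen presentation genes, which show peptides of the cell's own proteins to T cells, were higher in the SMAD4 siRNA library. Of 18 measured, 16 were above 0 and 16 had an interval above 1, with a median of 1.52-fold, on the scale of value + 1, that lay above all random lists. B2M, the invariant light chain, went from 24855 to 55801, a ratio of 2.25 (2.18 to 2.32). The heavy chains SLA-1, SLA-3 and SLA-5 had ratios of 2.83, 2.59 and 3.27, values that these near-identical genes may share through common reads. The list median stayed between 0.52 and 0.71 over the alternatives. None of these was set to remove shared reads, so that range does not bear on them. The immunoproteasome subunits PSMB9 and PSMB8 had 2.74 and 1.62, and the peptide transporters TAP1 and TAP2 had 1.14 and 1.42. MHC class II genes, over 7 members with few reads, had a median of -0.02, inside their range. The list shares no gene with the interferon-stimulated list.

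Interferon-stimulated genes were higher in the SMAD4 siRNA library. Leukocytes in that pool are argued against by their markers, though on few reads: leaving out CD14, whose high level would hide a small share, the 9 with reads summed to 81 and 67, a ratio of 0.751 (0.535 to 1.05) against 1.77 (1.73 to 1.81) for the summed interferon list. Both sums are of smallest whole reads, which can weigh genes unequally. Counting noise is argued against by the median of 1.10 in members with at least 100 reads. Gene length, as far as the smallest whole lengths show it, is argued against by a median above all (100%) random lists matched on it. Whether the response comes from the loss of SMAD4 or from the SMAD4 duplex or its transfection cannot be told apart with 1 duplex, whose list median is 1.27. A response to less SMAD4 may underlie it, and differences between the pooled animals were also not tested.

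Genes of TGF-beta response, matrix and actin were lower in the SMAD4 siRNA library. Across 9129 mRNA genes with at least 100 reads, those with a longer smallest whole length had lower ratios (Spearman correlation -0.14 across genes, which are not independent replicates). Medians were 0.00 in the 913 with the shortest such lengths and -0.17 in the 912 with the longest. With random lists matched on that length the list medians were at percentiles 0 for TGF-beta response, 0.39 for matrix and 0.11 for actin, which argues against it as the whole cause. That length is a lower bound, so an effect of true gene length stays open. For actin, fewer theca or stromal cells stay open: theca markers had a median of -0.16 over 6 members and -0.28 over the 4 with at least 100 reads, against the actin list's -0.32, and some of them are made by other cells too. Loss of SMAD4 may lower these genes, a hypothesis with no second knockdown here.

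Genes for digestive enzymes of the pancreas stood out in the control library. Of 13 acinar genes with reads, 12 were higher in the control library. Their smallest whole reads summed to 1059 against 282, or 0.00599% of such reads of the control library. The true share is not known, since these reads can fall short by factors that differ between genes. CPA1 had 501 and 11, CLPS 47 and 0 and CTRB2 146 and 45, but CEL 230 and 205. The test planned before further acinar genes were looked at was void, since its genes had 0 reads in both libraries. The 9 acinar genes other than CPA1 and CPB1, which had drawn attention to the pattern, had a median log2 ratio of -2.64 (-1.95 over 8 of them with those at 0 set to 3 reads), so RNA or reads of pancreas carried into the control library may explain them. No biological explanation was tested.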
